A study of Mus musculus with 2 samples.

How the data were processed

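Bulk RNA sequencing was done on RNA from whole mouse kidneys, with 1 library from control mice and 1 library from mice carrying a conditional knockout (CKO) directed at the proximal tubule, the nephron segment that reabsorbs most of the filtered solutes. The labels do not state how many animals went into each library. Per the labels' protocols, the mice ate standard chow, received no treatment, and libraries were made with a stranded mRNA kit. The submitters' processing notes name STAR 2.7.3a, HTSeq, Cufflinks 2.2.1, FastQC, DESeq2, edgeR and the mm10 genome build, without giving the role or order of each tool.

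The deposited raw table holds read counts per gene for 45777 NCBI gene IDs, as whole numbers that were not normalized, per the file headers and the values. The deposited FPKM values, from the same table per its file headers, are scaled by gene length and depth. The deposited TPM values, also named in the file headers, sum to a fixed total per library. A second table deposited by the authors holds normalized signal values for 19550 genes. Each value there equalled the read count divided by 1 constant per library, which was 30.1 for the control and 42.6 for the CKO library, with a largest relative deviation of 5.11e-15. These 19550 genes were the genes with a read in both libraries.

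The counts were the basis of the main values. Library sizes were scaled by TMM with edgeR 4.0.16 in R 4.3.3, over genes with a read in either library, which gave factors of 0.896 for the control and 1.12 for the CKO library and effective sizes of 30.1 and 42.6 (in Mreads). Values are CPM, computed from the effective sizes. Log2 ratios are CKO over control on the scale of CPM + 0.5, which understates the ratio of genes with few reads. Genes with 1 CPM or more in either library were called expressed. Everything else was computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and DESeq2 1.42.0 gave alternative size factors.

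With 1 library per group there is no replicate check, no test across animals and no p-value. Single values carry exact Poisson 95% intervals, and ratios carry exact Clopper-Pearson 95% intervals of the CKO share of both counts. These intervals cover counting error only, compare the 2 libraries and not the conditions, and leave out the variation between animals. A gene with 0 reads in the control was compared with a floor of 3 reads in that library, or 0.0996 CPM, and its ratio is given as a lower bound.

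Before the data were examined, 50 gene lists were fixed, each a pathway, a cell type or a gene class, along with the rule for named genes. That rule takes Inmt, then the 12 genes higher and the 12 lower in the CKO library whose 95% ratio interval stays farthest from 1, leaving out predicted and unnamed gene models, and 2 to 4 of the members with the largest log2 ratio in each list, plus the most abundant member, by the mean of both libraries, for marker lists. Some genes that this rule selects are not reported here. A list was described by the median log2 ratio of its expressed members and by the percentile of that median among 10000 random lists of the same size, matched on mean expression in 20 bins. Random lists were drawn from all expressed genes, with none left out. A change shared by many genes of similar abundance therefore also moves the random lists. A list under the 1st or over the 99th percentile was called apart from random lists, as a description of these libraries. Of the genes in a list, 46 were in more than 1 list. List symbols absent from the table were looked up by NCBI ID. None of the symbols of the mitochondrial genome list matched, so the 13 protein-coding genes on the mitochondrial chromosome were taken by location after the data were seen.

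The steps were tested on simulated counts for the CKO and control comparison over 45777 genes, with the real library sizes and 200 genes changed 4-fold. Of 100 expressed genes simulated 4-fold higher, 100 came out at least 2-fold higher, and of 98 simulated 4-fold lower, 96 came out at least 2-fold lower. None (0) of 13866 unchanged genes passed 2-fold in either direction, and 2 of 100 unchanged lists of 20 genes fell outside the percentile limits. The simulation draws counting error only, and about as many genes rise as fall in it. It therefore does not test how the scaling behaves when most changes go the same way.

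Coordinates are those of the RefSeq annotation of GRCm38, the assembly that the mm10 build names, matched by NCBI gene ID for 45679 of 45777 genes. The alternatives tried were DESeq2 size factors, total counts, total counts without the 50 most abundant and the mitochondrial genes, pseudocounts of 0.1 and 2 CPM, no minimum and a minimum of 10 CPM, a 1.5-fold limit, the counting interval as a further limit, lists without sex-biased genes, means in place of medians, unmatched random lists and the authors' normalized table. The authors' TPM and FPKM values, a CKO library thinned to the control total, counts without genes at 0 and lists without tubular injury genes were added after seeing the data. The strand setting of the counting is not given in the sources used here, so genes that overlap another gene are uncertain, as are near-identical copies.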

Results

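The data comprised 2 RNA-seq libraries from whole mouse kidneys, 1 from control mice and 1 from mice with a proximal tubule conditional knockout of Inmt, and the comparison asks how kidney gene expression differs when Inmt is deleted in the proximal tubule. Inmt encodes indolethylamine N-methyltransferase, which moves methyl groups from S-adenosylmethionine to tryptamine and other small amines and to selenium and sulfur compounds. The control library held 33618076 counted reads and the CKO library 38136616. Reads fell on 20332 genes in the control and 22699 in the CKO library, and 15129 genes reached 1 CPM, the TMM-scaled read level used here, in either library. Mitochondrially encoded genes took 14.4% of control reads (exact 95% interval 14.38 to 14.40) and 10.8% of CKO reads (10.77 to 10.79). The 20 most abundant genes took 21.9% of control and 16.6% of CKO reads. Each group has 1 library, so none of the differences below has a replicate check.

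Inmt was 4.73-fold lower in the CKO library (95% counting interval 4.59 to 4.88), with 17678 reads in the control and 5283 in the CKO library. Its level was 587 CPM (exact Poisson interval 578 to 596) against 124 CPM (121 to 127), so that 21.1% of the control level remained. Its log2 ratio of -2.24 ranked 12 from the lowest among 15129 expressed genes, and 3 from the lowest among the 2071 genes with at least 100 CPM in the control. Inmt (NCBI gene 21743) lies on chromosome 6 at 55170627 to 55174990 (GRCm38), a span of 4364 bp, and no other expressed gene overlaps it. The counts cover the whole gene, and the labels do not say which part was deleted.

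Within 1000 kb of Inmt, 16 other named genes were expressed, of which 2 were at least 2-fold higher and 1 was at least 2-fold lower in the CKO library. The lower one was Ggct, a gamma-glutamylcyclotransferase of glutathione breakdown, at chromosome 6, 54985095 to 54992960, which lies 178 kb from Inmt. Ggct was 3.54-fold lower, with 1222 reads against 488. Gars, which lies between Ggct and Inmt, had a log2 ratio of 0.01, and Mindy4 on the other side of Inmt had 0.15. The water channel gene Aqp1, 161 kb away, had a log2 ratio of -0.20, which turned positive when total counts set the scale. The fixed list of Inmt neighbours had 11 expressed members with a median of 0.01, at the 44.0 percentile of matched random lists, and with DESeq2 size factors its median was -0.01. Its other members with large ratios were Ghrhr with 6 reads against 73 (8.60-fold higher, interval 3.77 to 24.2), Adcyap1r1 at -0.71 and Znrf2 at -0.67.

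**Figure D1:**
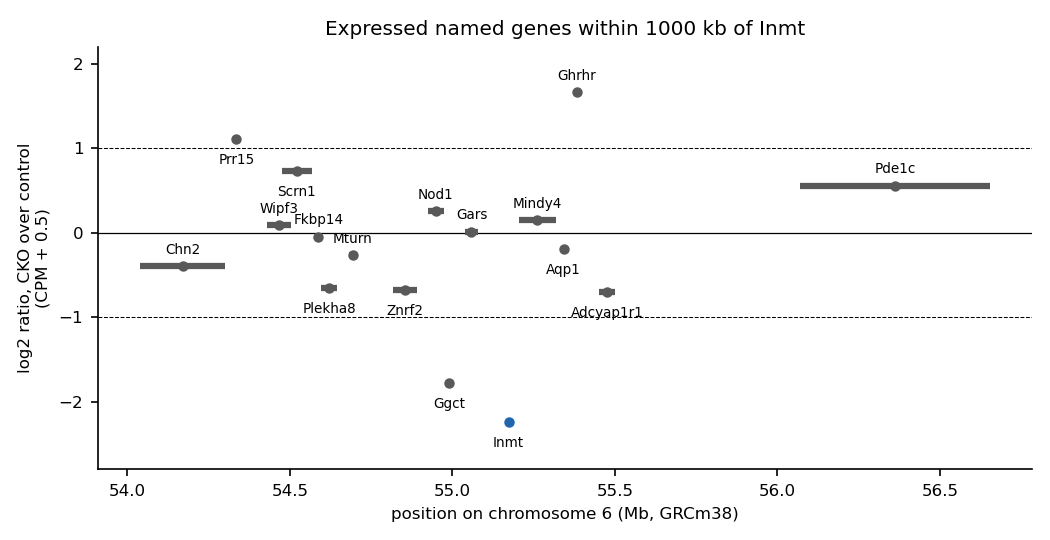
Log2 ratio of CKO over control (CPM + 0.5, vertical axis) against position on chromosome 6 (Mb, GRCm38) for Inmt and the 16 other named genes expressed within 1000 kb. Bars span each gene, points mark its middle and dashed lines mark 2-fold; Inmt (-2.24, blue) and Ggct (-1.78) lie below the lower line.

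Genes higher in the CKO library outnumbered genes lower there, with 1552 genes at least 2-fold higher, 251 at least 2-fold lower and 13326 in between. These counts, like those of the lists below, use the log2 ratio of CPM + 0.5, so a gene with few reads can have a plain ratio above 2 and not be counted. At least 4-fold, the numbers were 291 and 16. The higher genes had a median control level of 1.69 CPM, against 41.9 CPM for the lower genes and 18.9 CPM for all expressed genes. When the libraries were scaled by their total counts, the median log2 ratio of expressed genes moved from 0.01 to 0.32, and the counts became 2391 higher and 102 lower. The share of higher genes among those past 2-fold was then 95.9% in place of 86.1%. With a minimum of 10 CPM the counts were 573 and 182, a share of 75.9%, and with a pseudocount of 2 CPM they were 825 and 167, a share of 83.2%. List values below are therefore best read against their matched lists and, across scalings, against the median of all expressed genes. Between the authors' TPM and FPKM values, that median was 0.40 and 0.26.

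C3, the central complement component, went furthest among abundant genes, at 758 CPM in the CKO library (chromosome 17, 57203967 to 57228136) against 12.7 CPM, a ratio of 59.6 (53.9 to 66.1). Lcn2, a secreted iron-siderophore carrier and kidney injury marker, was 79.8-fold higher (45.5 to 155), on 12 against 1354 reads. Cxcl1, a chemokine that attracts neutrophils, was 90.3-fold higher (41.3 to 247). Serpina10, a protease inhibitor of the clotting system, was 73.2-fold higher, and Krt19, a keratin of simple epithelia, 55.1-fold. Aoc1, a diamine oxidase that degrades histamine and putrescine, was 38.2-fold higher (30.1 to 49.2), on 69 against 3725 reads, and it overlaps the gene model Gm44764. Ltbp2, an extracellular matrix protein, was 56.0-fold higher. The other 5 of the 12 leading genes were listed at 0 in the control. Against the floor of 3 reads, Pakap was at least 166-fold higher, the mucin gene Muc4 at least 98.8-fold, the urea transporter gene Slc14a2 at least 95.5-fold, the metalloproteinase inhibitor gene Timp1 at least 90.5-fold and the epithelial envelope gene Sprr1a at least 33.9-fold.

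Those zeros carry a limit of their own. Among 1401 genes with 30 to 59 reads in the CKO library, 101 had exactly 0 reads in the control and only 34 had 1 to 3 reads, an excess of zeros over low counts. Among genes with 100 or more reads in the CKO library, as Pakap, Muc4, Slc14a2, Timp1 and Sprr1a had, 20 had 0 in the control and 2 had 1 to 3. In the opposite direction, 2 genes had 0 and 1 had 1 to 3 among 1252 genes. The ratios of these 5 genes are lower bounds only if a listed 0 is a true count, which was not tested. Pakap shares its locus with Akap2, which had 7035 reads in the control and 7936 in the CKO library, both before scaling. Muc4 overlaps Muc20, so the split of reads is uncertain at both loci.

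Inmt was 1 of the 12 leading lower genes. Among the others, Car3, a carbonic anhydrase, was 8.66-fold lower (7.94 to 9.45), at 123 CPM against 14.2. Ccl28, a mucosal chemokine, was 7.15-fold lower (6.47 to 7.92). Acsm3, a medium-chain acyl-CoA synthetase, was 4.95-fold lower (4.82 to 5.09) at 770 CPM against 156, and Slco1a1, an organic anion transporter, 4.40-fold lower (4.29 to 4.52). Synpr was 12.6-fold lower, Gnrh1 7.90-fold, Cntnap5a 5.49-fold and Tmprss9 5.26-fold, each on 383 reads or fewer in the control. Rsc1a1 was 10.2-fold lower and Snrpn 9.97-fold lower, but both overlap genes with ratios near 1. Ddi2, which contains Rsc1a1, had a log2 ratio of 0.15, and Snurf, which shares transcripts with Snrpn, had 0.14, so the ratios of Rsc1a1 and Snrpn are uncertain. Acsm3 overlaps Eri2, and Tmprss9 overlaps Timm13.

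**Figure D2:**
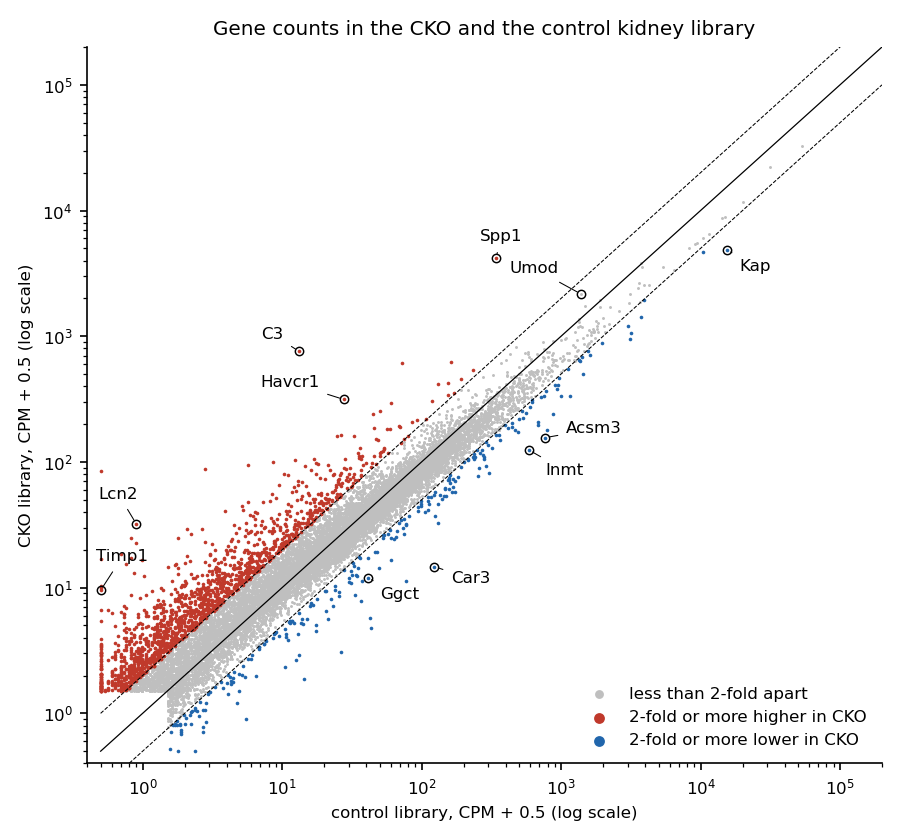
Level of each expressed gene in the control library (horizontal axis) and the CKO library (vertical axis), both as CPM + 0.5 on log scales, with 1 point per gene. Red points are the 1552 genes at least 2-fold higher and blue points the 251 at least 2-fold lower in the CKO library; the solid line marks equal levels, dashed lines mark 2-fold, and Inmt lies among the abundant lower genes.

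Tubular injury genes were the highest of the lists with 4 or more expressed members. With FPKM values the macrophage median was above the injury median, at 2.41 against 2.38. Of 25 expressed injury genes, 23 were at least 2-fold higher and none (0) was at least 2-fold lower. Their median log2 ratio of 2.61 lay above all 10000 matched lists. Spp1, the osteopontin gene and the most abundant member, went from 342 to 4196 CPM, a ratio of 12.3 (12.0 to 12.5). Havcr1, which encodes kidney injury molecule 1, went from 27.1 to 314 CPM, a ratio of 11.6 (10.8 to 12.5). Cd44, a hyaluronan receptor, was 18.0-fold higher, and Lcn2 and Krt19 belong to this list too. Hmox1, the heme oxygenase gene, was the 1 member below 0, at -0.56.

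The p53, cell cycle and immediate early lists were higher too. Of 15 p53 target genes, 7 were at least 2-fold higher, with a median of 0.92, above all 10000 matched lists, and Phlda3 (9.26-fold), Gdf15 (8.34-fold), Eda2r (9.59-fold) and the cell cycle inhibitor gene Cdkn1a (4.06-fold) led. Of 20 cell cycle genes, 15 were at least 2-fold higher, with a median of 1.48, also above all matched lists. Mki67, a proliferation marker, was 4.42-fold higher (3.78 to 5.19), Cenpf 6.19-fold and Top2a 4.40-fold, while Bub1 was listed at 0 in the control. With a minimum of 10 CPM, 9 cell cycle genes were left and their median was 0.50, at the 94.1 percentile. Immediate early genes had 13 of 19 members at least 2-fold higher and a median of 1.60, above all matched lists. These genes also respond to handling and time to freezing, a cause that was not tested. Socs3, a feedback inhibitor of cytokine signalling, was 18.9-fold higher, Egr2 24.1-fold, Atf3 9.31-fold and Egr1 5.21-fold.

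Macrophage markers had 13 of 14 members at least 2-fold higher, with a median of 2.51 that lay above all 10000 matched lists. The median became 2.53 with Ms4a7, at 0 in the control, set at its plain-ratio bound. Lyz2, the lysozyme gene of myeloid cells, was 18.1-fold higher (15.4 to 21.4), the monocyte chemokine receptor gene Ccr2 13.4-fold, Cd14 10.9-fold and Itgam 10.7-fold. Csf1r, the most abundant member, was 1.83-fold higher. Among lymphoid markers, the T and NK cell list had 5 of 7 expressed members at least 2-fold higher and a median of 1.24 at the 97.6 percentile, with Klrk1 on 7 against 90 reads, Lck on 15 against 114 and Il2rb, the most abundant, on 38 against 142. The B and plasma cell list had 2 expressed members, Ighm (3.58-fold higher) and Ebf1 (1.80-fold), with a median of 1.24 at the 94.5 percentile. The neutrophil list had 1, Csf3r, 5.85-fold higher on 22 against 182 reads, at the 95.8 percentile.

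Inflammation genes had 15 of 16 expressed members at least 2-fold higher, with a median of 1.90, above all matched lists. The median was 1.99 with 3 members at 0 in the control set at their plain-ratio bounds. Besides C3 and Cxcl1, the monocyte chemokine gene Ccl2 was 50.2-fold higher (27.1 to 105) and Ccl5 13.0-fold. Interferon response genes had 20 of 24 members at least 2-fold higher and a median of 1.80, above all matched lists. Oas2 was 9.46-fold higher, the transcription factor gene Irf7 6.38-fold, Ifi27l2a 7.01-fold and Gbp3 5.07-fold. Antigen presentation genes had 11 of 13 at least 2-fold higher and a median of 1.64, above all matched lists. The class II genes H2-Aa, H2-Eb1 and H2-Ab1 were 5.77-fold, 5.62-fold and 4.96-fold higher, and Cd74, their invariant chain, was 4.87-fold higher.

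Extracellular matrix genes had 20 of 27 members at least 2-fold higher and a median of 1.53, above all matched lists. The collagen cross-linking enzyme gene Lox was 9.98-fold higher and the matrix protease gene Mmp2 6.43-fold, next to Timp1. Among muscle genes, 1 of 4 expressed members was at least 2-fold higher, with a median of 0.73 at the 97.3 percentile, and Tagln, the most abundant, was 2.92-fold higher, Cnn1 2.49-fold on 21 against 74 reads (log2 ratio 0.90) and Des 1.49-fold.

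Proximal tubule markers were lower as a group, and matched lists of equally abundant genes were lower too. The matched lists could hold proximal tubule genes themselves, so they do not give a level free of a shared fall. Of 28 markers, 4 were at least 2-fold lower, none (0) was at least 2-fold higher and 25 had a log2 ratio below 0. Their median of -0.55 lay at the 1.23 percentile of matched lists, whose own median was -0.37, so the list was not apart by the fixed limit, although it was below the 1st percentile under 4 of 14 alternatives. The inositol oxygenase gene Miox was 2.27-fold lower, Acsm2, the most abundant marker, 2.24-fold at 4654 CPM in the CKO library, the organic anion transporter gene Slc22a6 2.24-fold and the nuclear receptor gene Hnf4a 2.06-fold. Markers of the S3 segment, the straight end part of the tubule, were apart, with 5 of 12 at least 2-fold lower and a median of -0.90, below all 10000 matched lists. Slc22a7 was 3.72-fold lower, Acy3 2.54-fold, Slc7a13 2.17-fold, Aadat 2.09-fold and Atp11a, the most abundant, 2.04-fold. Organic ion and drug transporters had 7 of 29 members at least 2-fold lower and 1 at least 2-fold higher, with a median of -0.63, below all matched lists, led by Slco1a1 and Slc22a7, with Slc22a30 2.81-fold lower and the efflux pump gene Abcc4 2.64-fold higher.

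Genes that male kidneys express more than female kidneys were the lowest list. Of 13 members, 11 were at least 2-fold lower and none (0) was higher, and the median of -1.54 lay below all matched lists. The androgen-regulated Kap was the most abundant, at 15529 CPM in the control and 4858 in the CKO library, 3.20-fold lower (3.18 to 3.21). Besides Acsm3 and Slco1a1, Cyp4a12a was 3.48-fold lower and Cyp2e1 3.28-fold. Cyp4a12a has a near-identical copy, Cyp4a12b, so their split is uncertain. Genes of the female-biased list had 4 of 8 members at least 2-fold higher and a median of 1.11, above all matched lists, with the prolactin receptor gene Prlr 6.68-fold higher, Slc7a12 5.11-fold, Cyp4a14 4.03-fold and Abcc3 3.72-fold, and with Cyp2a4, the most abundant, at -0.59. The 4 expressed Y-linked genes were present in both libraries, with a median of -0.19 at the 24.8 percentile (0.13 with total counts), and the most abundant, Ddx3y, had 2212 reads in the control and 2778 in the CKO library. The X inactivation transcript Xist had 0 reads in the control and 17 in the CKO library. Cytochrome P450 genes went both ways, with 8 of 26 at least 2-fold lower and 6 at least 2-fold higher, and a median of -0.41 at the 0.14 percentile. Cyp26b1, which degrades retinoic acid, was 12.1-fold higher. Without the members that are also in a sex-biased list, the P450 median was -0.11, at the 42.0 percentile.

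Of 3 lists around the enzyme's substrates, 2 were apart on the lower side, with members in both directions and medians no lower than those of the proximal tubule, S3 and transporter lists. Tryptophan and tryptamine genes had 4 of 19 expressed members at least 2-fold lower and 1 at least 2-fold higher, with a median of -0.43 at the 0.04 percentile, or -0.23 at the 1.65 percentile without the expression minimum. Afmid was 2.29-fold lower, Ido2 2.31-fold and Aadat, also an S3 marker, 2.09-fold, while Kynu, the kynureninase gene, was 2.74-fold higher. Selenium and sulfur genes had 2 of 21 members at least 2-fold lower and 2 at least 2-fold higher, with a median of -0.46 at the 0.14 percentile, and with mean values in place of the median the list lay at the 3.62 percentile. Msrb1 was 2.18-fold lower and Ethe1 2.06-fold, whereas the deiodinase gene Dio1 was 2.25-fold higher and Lrp8 2.16-fold. With TPM values the tryptophan and selenium medians were -0.03 and -0.04, where the median of all expressed genes was 0.40. Methyl group metabolism was not apart, with none (0) of 29 members at least 2-fold lower, 1 at least 2-fold higher and a median of -0.33 at the 2.78 percentile, or 0.09 with TPM values, and it was below the 1st percentile under 3 of 14 alternatives. Nnmt, a nicotinamide methyltransferase gene, had 4 against 51 reads, and Gnmt at -0.95, Shmt2 at -0.94 and Cbs at -0.93 were the lowest.

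Mitochondrial transcripts were lower throughout when scaled by TMM. The 13 protein-coding mitochondrial genes had log2 ratios from -0.82 for ND4 to -0.61 for ATP8, with a median of -0.72 at the 0.57 percentile, and COX1, the most abundant, went from 53213 to 32840 CPM. With total counts the mitochondrial median was -0.40. Nuclear genes of oxidative phosphorylation all lay below 0, 23 of 23, with a median of -0.40 at the 26.7 percentile, close to that of equally abundant genes; with TPM values the median was 0.01. Atp5b, at -0.52, and Sdha, at -0.51, were the lowest. Fatty acid oxidation and PPAR-alpha targets had a median of -0.31 at the 15.2 percentile, which became 0.01 with total counts. Of 27 members, 2 were at least 2-fold higher, Cyp4a14 and the kinase gene Pdk4 (2.54-fold), and 1, Ehhadh, was at least 2-fold lower (2.02-fold).

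Several metabolic lists were not apart from matched lists. Gluconeogenesis and glycolysis had a median of -0.13 at the 87.2 percentile, with 3 of 22 members at least 2-fold higher and 1 lower. The hexokinase gene Hk2 was 9.73-fold higher and Pfkfb3 2.72-fold, while G6pc, the last enzyme of glucose release, was 2.17-fold lower. Amino acid transport had a median of -0.09 at the 89.95 percentile, with 3 of 20 members at least 2-fold higher and 1 lower, among them Slc7a12 5.11-fold and Slc7a5 2.40-fold higher. NRF2 targets had a median of -0.16 at the 48.9 percentile, with 2 of 17 at least 2-fold higher and 1 lower, Ephx1 3.12-fold higher, Abcc4 2.64-fold higher and Osgin1 2.69-fold lower. Ferroptosis and iron genes had a median of -0.22 at the 19.1 percentile, with the transferrin receptor gene Tfrc 2.24-fold lower and Ptgs2 on 6 against 43 reads. The medians of these 4 lists turned positive with total counts. Cholesterol biosynthesis had a median of 0.04 at the 90.8 percentile, with Idi1 2.45-fold and Cyp51 2.25-fold lower. The unfolded protein and integrated stress response had a median of 0.02 at the 87.4 percentile, turning negative (-0.0010) with DESeq2 size factors, with Asns 2.80-fold higher and Trib3 on 14 against 60 reads. Aryl hydrocarbon receptor targets had a median of 0.14 at the 56.4 percentile, with Slc7a5 and Cyp1b1 (1.87-fold) highest. Renin-angiotensin and kidney hormone genes had a median of -0.27 at the 21.5 percentile, with Agt 8.34-fold higher, the vitamin D hydroxylase gene Cyp27b1 3.05-fold higher and Ace at -0.94, and Kl, the klotho gene, at -0.80; with TPM values the median was 0.08.

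Markers of the other nephron segments and resident cells had medians from -0.04 to 0.56. Collecting duct principal cell markers had 3 of 10 members at least 2-fold higher and a median of 0.56 at the 99.9 percentile (98.7 among unmatched lists), with Elf5 6.86-fold higher, St6gal1 2.34-fold, the water channel gene Aqp2 2.05-fold and Hsd11b2, the most abundant, at 0.35. Thick ascending limb markers had none (0) of 10 past 2-fold and a median of 0.37 at the 99.8 percentile, with Umod 1.57-fold and Cldn19 1.72-fold higher and Egf 1.62-fold lower, and their mean of 0.24 lay at the 94.1 percentile (their median at 94.8 among unmatched lists). Ribosomal protein genes had none (0) of 28 past 2-fold and a median of 0.11, above all matched lists, whose median was -0.26, but at the 81.5 percentile of unmatched lists. Rpl3 at 0.35 and Rps2 at -0.33 were farthest from 0, and Rps2 turned positive with TPM values. Intercalated cell markers had a median of 0.20 at the 98.0 percentile, with Aqp6 2.28-fold and Slc4a9 1.60-fold higher and Atp6v1b1, the most abundant, at 0.16. Podocyte markers had a median of 0.19 at the 90.3 percentile, with Cdkn1c at 0.86, Clic3 at 0.42 and Podxl, the most abundant, at 0.06. Endothelial markers had a median of 0.07 at the 94.9 percentile, with Kdr at -0.45, Tek at 0.26 and Plvap, the most abundant, at 0.08. Distal convoluted tubule markers had a median of -0.04 at the 81.8 percentile, which became 0.28 with total counts. The calcium channel gene Trpv5 was 4.51-fold higher, Calb1 was 1.60-fold lower and Wnk1, the most abundant, was at -0.04.

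Lists for blood, adjoining tissue and strain gave the following. Erythroid genes had 4 of 8 at least 2-fold lower and a median of -0.98, below all matched lists, and the haemoglobin genes Hba-a1 and Hbb-bs were 2.67-fold and 2.58-fold lower and Hba-a2 was at -1.43; Hba-a1 and Hba-a2 are near-identical copies. The adipocyte list had 2 expressed members, Car3 and Fabp4 (1.19-fold higher), with a median of -1.41 at the 0.13 percentile, and without the expression minimum 5 members gave 0.13. The adrenal list had 2, Star at 0.38 and Akr1b7 at 0.17, with a median of 0.28 at the 32.3 percentile. The urothelium list had 3 of 9, Krt19, Upk3b on 0 against 43 reads and Trp63 at 0.05, with a median of 1.59 at the 98.5 percentile. The median was 3.34 with Upk3b at its bound, a plain ratio without the added 0.5 CPM, so the 2 medians are not on the same scale. Genes that differ between laboratory strains had a median of -0.66 over 4 members at the 0.95 percentile, a call lost under 3 of the alternatives. Nnt, which C57BL/6J mice carry in a deleted form, had 7427 reads in the control and 7680 in the CKO library, a log2 ratio of -0.45 after scaling. Entpd4 and Entpd4b, near-identical copies, were at -0.84 and -0.86.

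Clock and heat shock genes also differed. In the list that peaks with Bmal1, 2 of 5 members were at least 2-fold lower and the median of -0.94 lay below all matched lists, with Arntl, the Bmal1 gene, 3.33-fold lower (2.88 to 3.87), Npas2 2.86-fold lower, Clock, the most abundant, at -0.58 and Cry1 against the others at 0.69. In the Per and Dbp phase list, 4 of 11 were at least 2-fold higher, with a median of 0.64 at the 99.98 percentile. Ciart was 7.78-fold higher, Dbp 3.99-fold, Bhlhe41 3.15-fold and Per1 2.59-fold, while Tef, the most abundant, was at 0.04. Nr1d1 at -0.18 and Hlf at -0.32 were below 0, but both were above 0 with TPM values. Heat shock genes had 4 of 13 at least 2-fold lower and 2 at least 2-fold higher, with a median of -0.83, below all matched lists. Hspa1a was 3.36-fold lower, its near-identical copy Hspa1b 3.07-fold and Hsph1 2.85-fold, whereas the small heat shock gene Hspb1 was 6.19-fold higher.

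**Figure D3:**
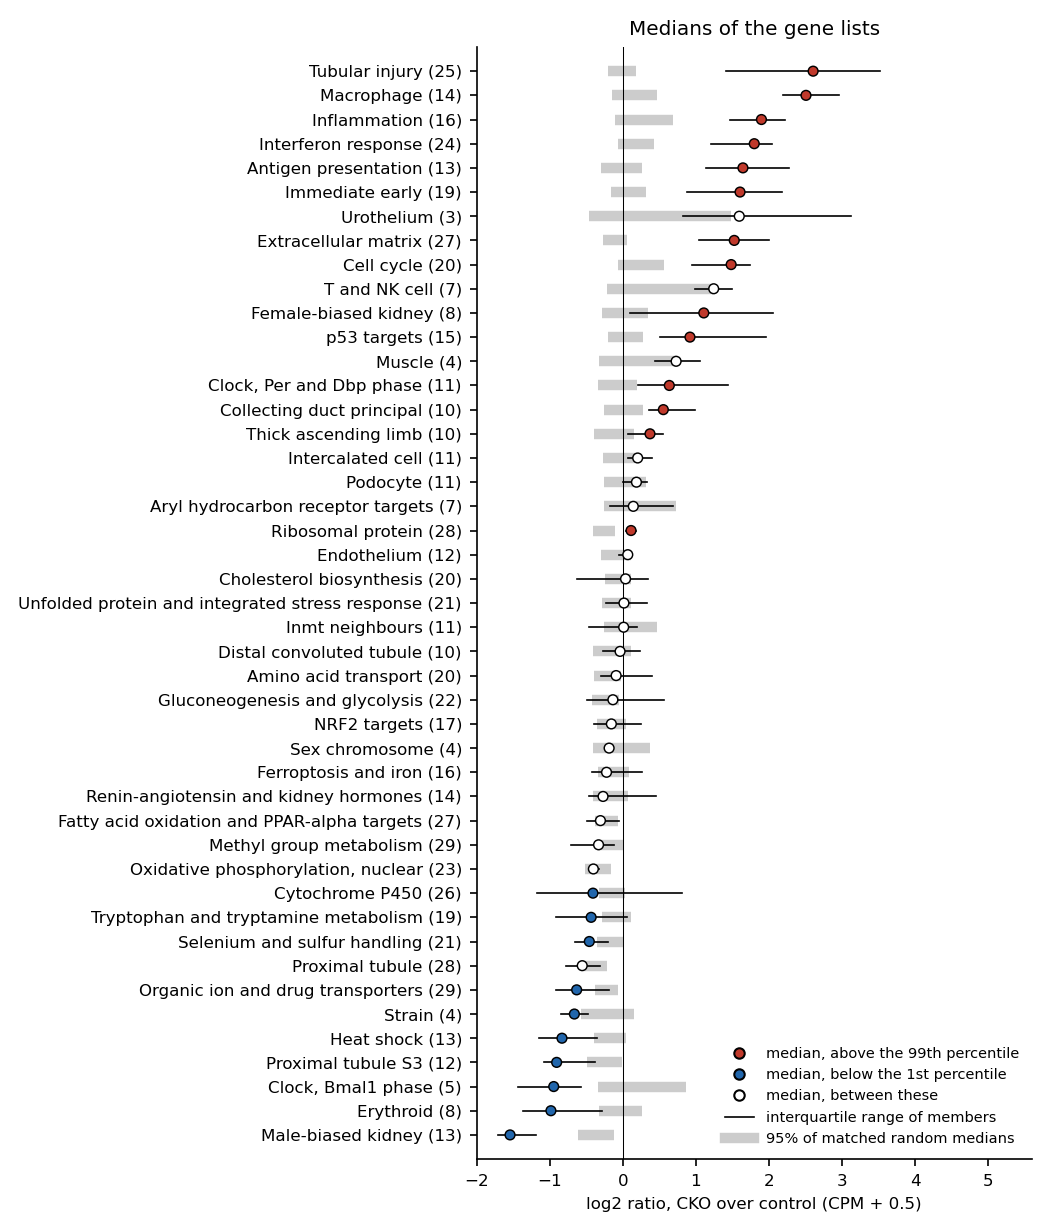
Median log2 ratio of CKO over control (CPM + 0.5, horizontal axis) for the 45 gene lists with 3 or more expressed members, whose number stands in parentheses. Points are medians, black lines the interquartile range of members and grey bars the middle 95% of medians of matched random lists; red and blue points lie over the 99th and under the 1st percentile, from Tubular injury at 2.61 down to Male-biased kidney at -1.54.

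By the fixed limit, 14 lists lay higher and 11 lower than matched random lists, and 24 were not apart. Percentiles describe these 2 libraries, since genes of a list share regulation and cells and are not replicates.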

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

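The authors' TPM and FPKM values, the thinned library, the counts without genes at 0 and the lists without injury genes were tried only after the data were seen. The other alternatives were planned. Among the planned ones, the authors' normalized table divides the counts by 30.1 and 42.6, nearly the same sizes as in the main setting. It could therefore hardly change the scale and is not a separate check of it. Inmt stayed below 0 in all 10 of its alternatives, at -1.92 with total counts, -2.04 with total counts without the 50 most abundant and the mitochondrial genes, -1.82 with TPM and -1.92 with FPKM, which were the moves beyond its counting interval. The number of genes at least 2-fold higher, 1552, became 2391 with total counts, 2613 with TPM, 825 with a pseudocount of 2 CPM, 573 with a minimum of 10 CPM (75.9% of genes past 2-fold against 86.1%) and 2920 at 1.5-fold. The number at least 2-fold lower, 251, became 102 with total counts, 158 with total counts without the top 50 and mitochondrial genes, 139 with TPM, 102 with FPKM, 167 with a pseudocount of 2 CPM and 1037 at 1.5-fold. The total-count moves follow from a scale that shifts every log2 ratio upward; for TPM and FPKM the cause was not tested. Of the 1552 higher genes, 1519 stayed past 2-fold when the CKO library was thinned to the control total, and 1474 remained without genes at 0 in either library. Every gene past 2-fold in the main setting also had a counting interval beyond 1.5-fold, 1552 and 251 genes. The pseudocount and the expression minimum already require larger plain ratios of genes with few reads. This further limit could therefore hardly remove a gene, and the unchanged counts are not a separate check. The 24 leading genes kept their sign in every setting that gave them a value. They were picked for ratios far from 1, so this outcome was all but fixed in advance.

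Between 22 and 28 lists were apart from random lists across 14 alternatives, against 25 in the main setting. Of these 25, 16 kept their call, and 18 of the 24 others stayed not apart, in every alternative that gave them a value. Among these 25, only the adipocyte list turned its sign, to 0.13 with no minimum, as 3 further members with few reads entered; the lists whose medians turn sign under another scaling were all among the others. The calls lost elsewhere were those of the cell cycle list (minimum of 10 CPM), the P450, selenium, tryptophan, strain, thick ascending limb, principal cell and ribosomal lists, each under 1 to 4 alternatives. Calls were gained by the urothelium list under 6 alternatives, the proximal tubule list under 4, the methyl group list under 3, the T and NK cell list under 2, and the fatty acid oxidation and oxidative phosphorylation lists under 1 each. No paired analysis was possible because each group has 1 library, and for the same reason the edgeR and DESeq2 tests with their filter and leave-one-out alternatives were not run. Depth limits genes near 1 CPM, where 1 library holds about 30 to 43 reads.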

Other observations

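All tests in this part were chosen after the results they bear on had been seen. Gene families defined by the shared stem of their symbols gave further groups: of 265 families with 8 or more expressed genes, 34 lay above the 99th percentile of matched random lists and 17 below the 1st. Toll-like receptor genes (Tlr stem) had 9 of 11 at least 2-fold higher and a median of 1.44, C-type lectin genes (Clec) 10 of 16 and a median of 1.30, matrix metalloproteinase genes (Mmp) 6 of 11 and a median of 1.30, and guanylate-binding protein genes (Gbp) 5 of 11 and a median of 0.93. Among epithelial families, keratin genes (Krt) had 5 of 9 at least 2-fold higher and a median of 1.05, and the tight junction claudin genes (Cldn) 5 of 14 and a median of 0.66, with Cldn4, Cldn3 and Cldn7 the highest and Cldn18 and Cldn2 the lowest. Annexin genes (Anxa) had a median of 0.85 and Klf transcription factor genes a median of 0.59.

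On the lower side, carboxylesterase genes (Ces) had 5 of 10 at least 2-fold lower and 1 at least 2-fold higher, with a median of -0.94, and glucuronosyltransferase genes (Ugt) had 4 of 14 lower and 3 higher, with a median of -0.66. Monocarboxylate transporter genes (Slc16a) had a median of -0.59. These 3 families stayed below 0 under every scaling tried. Mitochondrial ribosomal protein genes were below matched lists too, with 50 Mrpl genes at a median of -0.30 and 30 Mrps genes at -0.30. Both medians were positive with total counts, at 0.02 and 0.01, where the median of all expressed genes was 0.32.

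Inmt was lower in the CKO library along with other proximal tubule and male-biased genes. Of 52 expressed members of the proximal tubule, S3 and male-biased lists, 1, Acsm3, was lower than Inmt, by a difference of -0.065 on the log2 scale. The deletion named in the labels is 1 candidate explanation for the Inmt ratio, and a shared fall with these genes is another that could account for part of it; with 1 library per group and an untargeted gene as low as Inmt, the 2 cannot be told apart from these values. Acsm3 is a member of the male-biased list, and the lowest members of the proximal tubule and S3 lists were at -1.18 and -1.86. All members other than Acsm3 had higher ratios than Inmt, so the ratio of Inmt is not the typical one of these lists.

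Injury, immune and matrix genes were higher in the CKO library although the labels record no treatment. A lower share of proximal tubule RNA alone would raise markers of the other cell types alike, and the macrophage median exceeded the highest of the endothelial, podocyte and intercalated medians by 2.30, with the lower quartile of macrophage markers at 2.19 against an upper quartile of at most 0.40, which argues against it as the whole cause. The principal cell and thick ascending limb markers had higher upper quartiles, at 0.99 and 0.55, which leaves room for a lower share to add to the pattern but stays below 2.19. Adjoining fat, adrenal, urothelium or lymph node would bring its abundant transcripts. The median CKO level over 39 members of these tissues' lists was 0.141 CPM, with 9 at 1 CPM or more. That median pools all these tissues and could stay low with a single tissue present, so it cannot decide. The most abundant member, Fabp4, stood at 48.5 CPM, which argues against adjoining tissue for abundant genes such as C3 at 758 CPM. Adjoining tissue stays open for genes at lower levels such as Cxcl1 at 18.0 CPM. It stays open too for the urothelium list, with a median log2 ratio of 1.59. That median rests on the 3 of 9 members that reached 1 CPM in either library, and of these Krt19 is also in the injury list. The loss of Inmt may underlie the pattern, and so may a difference between the sampled kidneys that is unrelated to genotype, and with 1 library per genotype these stay open.

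The 2 antiphase clock lists were apart in opposite directions, with a difference of medians of 1.58 against a middle 95% of -0.96 to 0.32 for matched random pairs. Collection at a different time of day could give this, as could a genotype effect on the clock. The labels used here give no collection times and each group has 1 library, so these cannot be told apart. Nr1d1 and Hlf, at -0.18 and -0.32 but above 0 with TPM values, were far below Dbp and Ciart, and Cry1 went against its own list at 0.69.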
